A study of Homo sapiens with 12 samples.

How the data were processed

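Messenger RNA was sequenced from SUDHL6 cells, an established human cell line from a diffuse large B-cell lymphoma of germinal centre type. Per the labels, cells received vehicle (0.01% DMSO) or 200 nM GSK591, a small-molecule inhibitor of the arginine methyltransferase PRMT5, for 24 h or 96 h. Each of the 4 groups held 3 samples. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase, selected on oligo-dT beads and made into libraries with the Illumina TruSeq RNA kit. Nothing in the labels says that the 3 samples of a group came from separate cultures, so the p-values given here measure the spread between these samples, which may be technical.

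The authors deposited raw counts of reads per gene symbol, 1 table for each time, with 23368 symbols in common. Per the submitters' processing notes, STAR, HTSeq and edgeR were used and the genome build was hg19 (GRCh37). Their versions, the annotation, the strand setting and any filter are not given in the sources used here. The authors also deposited, for each time, a table of log2 fold changes of GSK591 over vehicle, average log2 CPM, p-values and their adjusted values, per the file headers. The test behind those tables is not given in the sources used here. Since the genome used here for gene properties is another build, genes are named by symbol and no coordinates are given. Without a stated strand setting, a gene and an overlapping or antisense partner cannot be told apart, and values of near-identical copies, such as HLA and histone genes and genes named by LOC numbers, are uncertain.

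Total counts ran from 48.5 to 64.4 M (M, mega) in 11 libraries, and vehicle replicate 1 at 96 h held 547.9 M, 10.2 times the median of the others. Before averaging, replicates of a group were compared by chi-square over genes. The statistic per degree of freedom lay between 2.2 and 39.8 for the 12 pairs, so no pair agreed within sampling noise and all 12 samples were kept. The columns of the count tables all matched a sample by name.

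Each time was fitted on its own with its 6 samples, since the times were deposited as separate tables. Genes were kept with edgeR's filterByExpr, library sizes were scaled with TMM factors, and groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. "Called" means past that threshold. The standard error of a log2 fold change was its size divided by the square root of the F statistic. The difference between the times (the 96 h log2 fold change minus the 24 h one) was tested in a fit of all 12 samples with 4 group means. Because each effect is taken against the vehicle of its own time, a shift shared by all 6 libraries of a time cancels in it. CPM here follow TMM scaling and are given as mean ± SD over 3 libraries.

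Before the data were examined, 19 gene lists, the rule for named genes, the designs and most of the other fits listed below were fixed. The lists cover the PRMT5 complex and other arginine methyltransferases, spliceosome assembly by Sm, LSm and SMN-complex proteins, BCL6-repressed genes, germinal centre identity, plasma cells, p53 targets, S phase, G2 phase and mitosis, homologous recombination and Fanconi repair, MYC and ribosome biogenesis, the integrated stress response, cholesterol synthesis, interferon-stimulated genes, MHC class II, B-cell activation and NF-kB, the BCL2 family, replication-dependent histones, markers of other cell types and mitochondrially encoded transcripts. Lists with at least 5 tested members were compared with the other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over 17 lists. The test was repeated with the correlation estimated from the data, and with fry, which asks whether a list's genes move on balance one way and compares them with no other genes. Members were counted as called over all genes tested and, separately, adjusted over the list alone.

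Genes are named by this rule. At each time these were PRMT5, WDR77, BCL6, MYC, PRDM1, CDKN1A, MDM2 and CCND2; the 5 largest rises and 5 largest falls past the threshold, with an average log2 CPM of at least 3 and groups whose values do not overlap; and the 2 members of each list with the smallest p-value. For the difference, the 3 most positive and 3 most negative values past the threshold with an average log2 CPM of at least 3 were named. Other members named as examples were chosen after their values were seen. Some genes that the rule selects are not reported here.

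The fits were tested on simulated counts with the means, library sizes and spread of the real libraries. The changed genes there were a small random part of the genes tested, all above a low level of expression. They were far fewer than the genes called in the real data. The shares below hold for that setting, so they are no measure of the recovery or the false calls in the real data. At 24 h (13173 genes), 84% of genes changed 1.2-fold and 100% of those changed 1.5-fold were recovered. At 96 h (13514 genes) the shares were 26% at 1.2-fold, 96% at 1.5-fold and 100% at 2-fold, and for the difference (13665 genes) 22%, 92% and 98%. False calls made up 7.25%, 8.52% and 3.11% of all calls in the simulated 24 h, 96 h and difference data. With an estimated correlation, camera called a simulated list shifted by 0.5 in each of the 3 (adjusted p = 0.00214, 0.000951 and 3.73e-06). Genes were drawn independently there, whereas genes of real lists moved together, such as S phase and DNA replication at 96 h (estimated correlation 0.861). At 24 h the median log2 fold change of that list was -0.09, a much smaller shift. The simulation therefore gives no measure of how readily camera calls the real lists.

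Alternatives were RLE factors or library size alone in place of TMM, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 5 CPM in 3 samples, a threshold of 0.01, the replicate number as a block, each library left out in turn, and all 12 samples in 1 fit for the effect at each time. After the data were seen, a fit with the deep library thinned to 51.8 M and a fit without both 96 h libraries numbered 2 were added. GC content and transcript length were the medians over the GENCODE release 29 transcripts of a symbol, found for 88.4% of the genes tested. Figures were drawn with matplotlib 3.10.9. The mitochondrially encoded transcripts matched 0 symbols of the count tables, so that list was not analysed here.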

Results

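Poly(A)-selected RNA of SUDHL6 lymphoma cells was counted per gene in 12 libraries, 3 for each combination of treatment (vehicle or 200 nM GSK591) and time (24 h or 96 h). The 6 libraries of 24 h held between 49.9 and 57.9 M counts (M, mega). At 96 h the vehicle libraries held 547.9, 51.8 and 48.5 M and the GSK591 libraries 50.4, 64.4 and 54.5 M. EEF1A1, a translation elongation factor, was the most abundant gene in every library and took 1.26% to 1.72% of the counts. The series title ties PRMT5 to BCL6, the transcriptional repressor that sets the germinal centre B-cell programme, and the comparisons ask which transcripts differ from vehicle after a short and a longer exposure to the inhibitor. Markers of T cells, myeloid cells, fibroblasts and epithelium stayed below 1 CPM on average in every group.

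After 24 h the treated cells differed from vehicle by many small changes. The largest rises among well-expressed genes were in NEIL1, a DNA glycosylase (log2 fold change 0.48 ± 0.07 SE), NFKBID, a nuclear regulator of NF-kB (0.43 ± 0.05), PRPF3, a splicing factor of the U4/U6 particle (0.42 ± 0.03), the small nucleolar RNA SNORD104 (0.42 ± 0.05) and SMNDC1, a spliceosome assembly factor (0.35 ± 0.03). PRPF3 went from 72.2 ± 1.26 to 96.8 ± 2.48 CPM (SD, n = 3). The largest falls among the same genes were in the uncharacterized LOC730101 (-0.53 ± 0.07), the phosphodiesterase subunit gene PDE6B (-0.52 ± 0.05), the endogenous retroviral gene ERV3-1 (-0.48 ± 0.04), HSD17B8, an enzyme of mitochondrial fatty acid synthesis (-0.48 ± 0.06), and ENTPD5, a nucleotide diphosphatase of the endoplasmic reticulum (-0.46 ± 0.07). The adjusted p of these 10 genes in edgeR's quasi-likelihood test lay between 3.18e-08 for PRPF3 and 0.000221 for ENTPD5, and by the rule that named them the 3 treated and 3 vehicle values did not overlap.

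Across 13173 genes tested at 24 h, 1940 were called, 980 higher and 960 lower, and 17 of them by 2-fold or more. The median size of a called change was 0.15 on the log2 scale. With library size alone in place of TMM the split was 563 higher and 1220 lower, so the near-even split rests on the scaling. These calls use the spread of the 24 h libraries (biological coefficient of variation 2.35%). With all 12 samples in 1 fit, which brings in the wider spread at 96 h, 29 genes were called, and 41 of the 44 named genes called at 24 h were lost. Leaving out 1 library moved the count to 980 without GSK591 replicate 1, 1041 without GSK591 replicate 3 and 1068 without vehicle replicate 2. In the authors' deposited table, 1811 genes had an FDR under 0.05 at 24 h, 543 higher and 1268 lower, and 1495 of them were called here. Its log2 fold changes correlated with those here at r = 1. For WDR77 and MDM2 they were -0.073 and 0.10, the same as with library size alone, against -0.055 and 0.118 with TMM. The uneven split in that table thus goes with the scaling.

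The drug target and the genes of the BCL6 axis moved little at 24 h. PRMT5 stood at 127 ± 5.10 CPM in vehicle and 128 ± 1.38 in treated cells (log2 fold change 0.00 ± 0.03, adjusted p = 0.984), and neither its partner WDR77 (-0.05 ± 0.02, adjusted p = 0.126) nor BCL6 (0.04 ± 0.02, adjusted p = 0.241), MYC (0.05 ± 0.03, adjusted p = 0.186) nor the cell cycle inhibitor CDKN1A (-0.13 ± 0.06, adjusted p = 0.166) passed edgeR's test. CDKN1A was called lower with the replicate block (adjusted p = 0.000531), with no filter (adjusted p = 0.00647), and without vehicle replicate 1 or GSK591 replicate 2 (-0.22 and -0.20, adjusted p = 0.00954 and 0.00503), so whether it changed at 24 h is left open. WDR77 was called lower with library size alone (-0.07, adjusted p = 0.0455). PRDM1, which drives plasma cell differentiation, was near the floor at 0.846 CPM in vehicle and 0.655 in treated cells and was not called (adjusted p = 0.201), nor was the cyclin gene CCND2 (adjusted p = 0.79). MDM2, a ubiquitin ligase gene, rose by 0.12 ± 0.03 (adjusted p = 0.0267), with overlapping groups. Its call was lost without vehicle replicate 1, vehicle replicate 2, GSK591 replicate 1 or GSK591 replicate 3 (adjusted p = 0.116, 0.128, 0.0569 and 0.164), and its adjusted p ran from 0.000306 to 0.355 over the alternatives. Of the PRMT5 complex and other arginine methyltransferases, 2 of 12 tested genes rose, 1 fell and 9 were not called, and the counts adjusted over the list alone were also 2 and 1. Of the BCL6-repressed genes, 4 of 24 rose, 0 fell and 20 were not called, with 4 higher adjusted over the list alone. Neither list was called by camera (adjusted p = 0.685 and 0.234).

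Proliferation genes were lower at 24 h. Of 35 S phase and DNA replication genes, 17 fell and 0 rose over all genes tested, and 24 fell and 1 rose adjusted over the list alone. Examples were RRM2, the regulatory subunit of ribonucleotide reductase (-0.30 ± 0.03), and POLA1, the catalytic subunit of DNA polymerase alpha (-0.20 ± 0.03). The list was called by camera (median log2 fold change -0.09, adjusted p = 2.2e-07), but not with an estimated correlation (adjusted p = 0.515 with an estimated correlation). Among 30 genes of G2 phase and mitosis 9 fell and 0 rose (10 and 1 adjusted over the list alone), including HMMR and TOP2A (-0.22 ± 0.04 and -0.10 ± 0.02). This list was called with adjusted p = 0.0102 (adjusted p = 0.53 with an estimated correlation), and the call was lost without vehicle replicate 1 (adjusted p = 0.0715). In the homologous recombination and Fanconi list 6 of 27 genes fell, such as FANCI and FANCD2 (-0.24 ± 0.03 and -0.22 ± 0.03), while BRCA2 and ATM rose (0.25 ± 0.05 and 0.12 ± 0.03). Adjusted over the list alone 9 fell and 2 rose, and camera called the list lower (adjusted p = 0.0102, and adjusted p = 0.515 with an estimated correlation). Of 24 genes of the integrated stress response, 5 fell and 0 rose by either adjustment, over all genes or adjusted over the list alone, among them the transcription factor ATF5 (-0.21 ± 0.04) and the serine synthesis enzyme PSAT1 (-0.16 ± 0.03). That list was called lower as well (adjusted p = 0.012, and adjusted p = 0.515 with an estimated correlation).

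A further 3 lists were called higher at 24 h. In germinal centre B-cell identity 11 of 29 genes rose and 3 fell (13 and 3 adjusted over the list alone). MYBL1, a transcription factor of germinal centre B cells, rose by 0.27 ± 0.03 and the B-cell receptor subunit gene CD79B by 0.14 ± 0.02. Camera gave adjusted p = 0.0033 for this list (adjusted p = 0.515 with an estimated correlation). In cholesterol synthesis 7 of 22 genes rose and 0 fell (14 and 0 adjusted over the list alone), with SREBF2, the transcription factor of the pathway, at 0.10 ± 0.02. Camera gave adjusted p = 0.000194 (adjusted p = 0.515 with an estimated correlation). Among Sm, LSm and SMN-complex genes 4 of 29 rose and 0 fell (5 and 0 adjusted over the list alone), among them SNRNP70 of the U1 particle (0.16 ± 0.02). That camera call stood near the threshold (adjusted p = 0.0496, and adjusted p = 0.53 with an estimated correlation). It was lost with library size alone, the filter of at least 5 CPM in 3 samples, and the replicate block (adjusted p = 0.165, 0.155 and 0.0684). The call was also lost without vehicle replicate 3, GSK591 replicate 2 or GSK591 replicate 3 (adjusted p = 0.399, 0.119 and 0.118). With fry, 2 lists were called at 24 h, germinal centre identity and cholesterol synthesis (adjusted p = 0.0191 for each).

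The remaining lists were not called by camera at 24 h. In the plasma cell list 2 of 19 genes rose and 5 fell (3 and 6 adjusted over the list alone), with XBP1, the transcription factor of secretory cells, lower by -0.34 ± 0.05 (list adjusted p = 0.342). Among p53 targets 4 of 29 rose and 6 fell (6 and 7 adjusted over the list alone), with ZMAT3 at 0.15 ± 0.03 and XPC at -0.14 ± 0.03 (list adjusted p = 0.428). In MYC and ribosome biogenesis 2 of 25 rose and 2 fell (5 and 3 adjusted over the list alone), with the methyltransferase gene NOP2 at 0.16 ± 0.02 and CAD, the pyrimidine synthesis enzyme, at -0.14 ± 0.02. This list had adjusted p = 0.0877 and passed without vehicle replicate 2 or GSK591 replicate 1 (adjusted p = 0.0129 and 0.0317). In the interferon list 1 of 18 rose and 2 fell by both adjustments, including adjusted over the list alone, with MX2 and OAS2 at -0.15 ± 0.03 each (list adjusted p = 0.758, and 0.0238 without GSK591 replicate 1). For that list the median (0.01) and mean (0.08) were positive while camera's direction was down, and without GSK591 replicate 1 the median turned to -0.14. In MHC class II 2 of 13 rose and 2 fell (2 and 3 adjusted over the list alone), with HLA-DOA at -0.19 ± 0.02 (list adjusted p = 0.508). B-cell activation and NF-kB had 4 of 21 higher and 0 lower (6 and 0 adjusted over the list alone; list adjusted p = 0.342). The BCL2 family had 1 of 15 higher and 1 lower by both, including adjusted over the list alone (list adjusted p = 0.399). The replication-dependent histones had 2 of 13 higher and 1 lower, also when adjusted over the list alone (list adjusted p = 0.406). Of the markers of other cell types 1 gene, CD14, had enough counts to be tested and was not called (adjusted p = 0.448).

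After 96 h the changes were larger and more numerous. Among well-expressed genes (average log2 CPM of at least 3), rises were led by SPOCK2, an extracellular matrix proteoglycan (log2 fold change 1.90 ± 0.38), TXK, a TEC-family tyrosine kinase (1.83 ± 0.18), ENPP3, an ectonucleotidase (1.77 ± 0.14), the synaptotagmin gene SYT11 (1.73 ± 0.32) and the scaffold protein gene AHNAK2 (1.51 ± 0.27). ENPP3 stood at 47.5 ± 6.77 CPM in vehicle and 163 ± 27.9 in treated cells (SD, n = 3). The average covers both groups, and SPOCK2, TXK and AHNAK2 passed it through the treated libraries. Their vehicle means were 5.33, 4.65 and 5.47 CPM. SPOCK2 stood at 20.5 ± 9.83 CPM in treated cells (SD, n = 3). Falls among the same genes were led by RRM2 (-1.77 ± 0.21), from 202 ± 34.4 to 58.9 ± 19.8 CPM, FAH, the last enzyme of tyrosine breakdown (-1.42 ± 0.19), the repressor E2F7 (-1.37 ± 0.28), OXCT1, an enzyme of ketone body use (-1.30 ± 0.15), and HSD17B8 (-1.30 ± 0.19). The adjusted p of these 10 genes in edgeR's quasi-likelihood test lay between 0.000293 for ENPP3 and 0.00617 for E2F7. By the rule that named them, their groups did not overlap. PRPF3 was again higher, at 0.89 ± 0.05.

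Across 13514 genes tested at 96 h, 5437 were called, 2792 higher and 2645 lower. Of these 488 changed 2-fold or more, 352 higher and 136 lower, and the median size of a called change was 0.41. The coefficient of variation was 8.19%. Without GSK591 replicate 1 the count was 3438 and without vehicle replicate 2 it was 3507. The vehicle and the treated library numbered 2 stood apart from the other libraries of their groups, and with both left out 8201 genes were called. For S phase and DNA replication the mean log2 CPM of vehicle replicate 2 was 0.15 relative to the vehicle mean, against -0.08 and -0.07 in replicates 1 and 3. GSK591 replicate 2 was at -0.44, against -0.82 and -0.71. Libraries of 1 group thus differed in a list that also differed with treatment, and both numbered 2 were shifted upwards. With the deep vehicle library thinned to the depth of the others the count was 5264. In the authors' deposited table for 96 h, 5322 genes had an FDR under 0.05, 2864 higher and 2458 lower, and 4847 of them were called here.

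**Figure D1:**
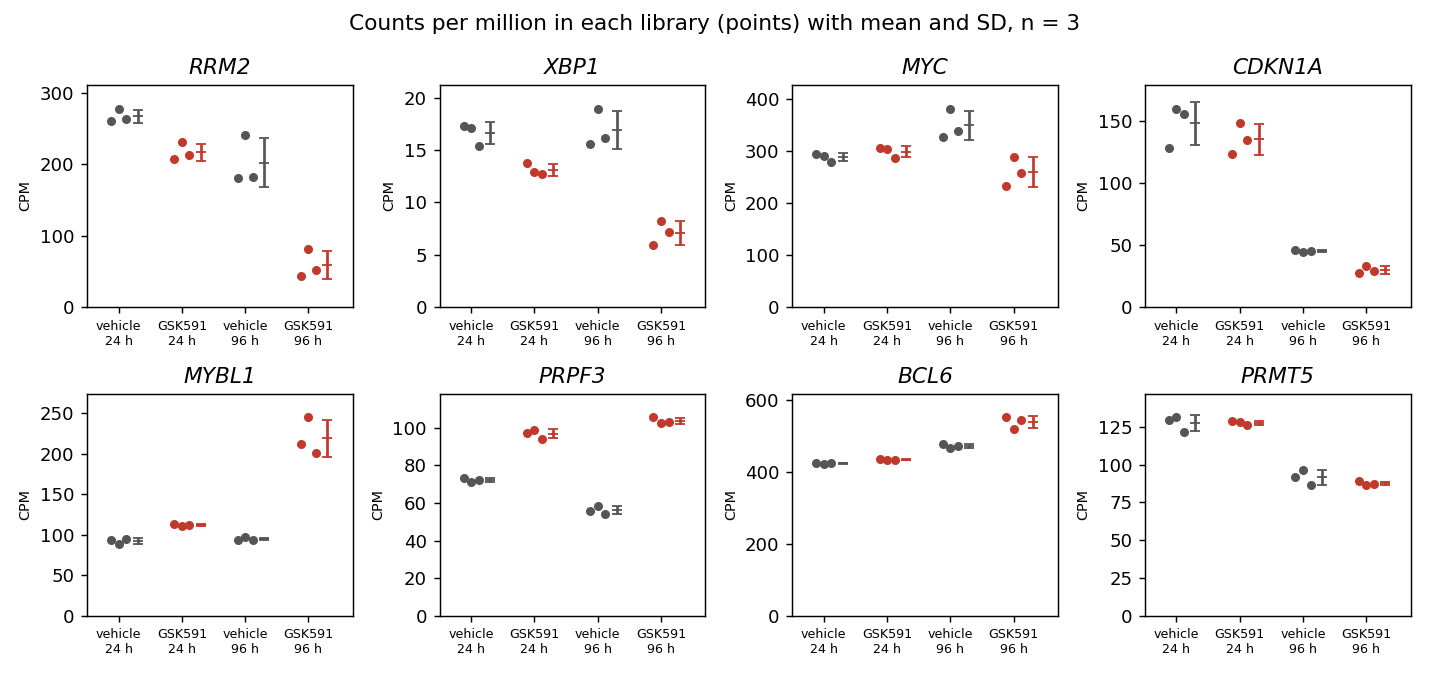
CPM (vertical axis, from 0) of 8 genes in each of the 12 libraries by group (horizontal axis), as points, with the mean and SD of each group of 3 beside them, grey for vehicle and red for GSK591. RRM2 and XBP1 were lower at both times and MYBL1 and PRPF3 higher at both, while PRMT5 was called at neither.

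Of the genes fixed in advance, 6 were called at 96 h. BCL6 rose by 0.19 ± 0.05, from 472 ± 4.97 to 539 ± 16.4 CPM (SD, n = 3), with adjusted p = 0.0174 in edgeR's test. The BCL6 call was lost without vehicle replicate 1, vehicle replicate 3, GSK591 replicate 1 or GSK591 replicate 3 (adjusted p = 0.0682, 0.0783, 0.0742 and 0.0593) and with no filter (adjusted p = 0.0606), and its adjusted p ran from 0.000762 to 0.0783 over the alternatives. MYC fell (-0.43 ± 0.09, adjusted p = 0.00652), as did CDKN1A (-0.59 ± 0.08, adjusted p = 0.00122) and WDR77 (-0.37 ± 0.06, adjusted p = 0.0026), and MDM2 rose (0.26 ± 0.05, adjusted p = 0.00632). CCND2 rose by 0.68 ± 0.19 at a low level, from 1.15 to 1.92 CPM (adjusted p = 0.0193), and lost its call without vehicle replicate 2 or 3 or without GSK591 replicate 1 or 3 (adjusted p = 0.0538, 0.0541, 0.07 and 0.0636, within a range from 0.0017 to 0.07 over the alternatives). PRMT5 (-0.06 ± 0.05, adjusted p = 0.373) and PRDM1 (0.40 ± 0.24, adjusted p = 0.22) were not called.

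The proliferation lists were lower at 96 h. In S phase and DNA replication 31 of 35 genes fell and 1 rose (32 and 1 adjusted over the list alone), with a median log2 fold change of -0.66. Besides RRM2, POLA1 fell by 0.82 ± 0.09 and the helicase component GINS2 by 0.66 ± 0.07. Camera gave adjusted p = 2.47e-10 (adjusted p = 0.542 with an estimated correlation). In G2 phase and mitosis 19 of 30 fell and 0 rose (21 and 0 adjusted over the list alone), among them the kinesin KIF20A (-0.76 ± 0.13) and cyclin A (CCNA2, -0.69 ± 0.13), with adjusted p = 3.69e-05 (adjusted p = 0.542 with an estimated correlation). In homologous recombination and Fanconi repair 15 of 27 fell, such as FANCI (-0.90 ± 0.11), and 1 rose, the damage kinase gene ATM (from 346 ± 35.5 to 690 ± 121 CPM, SD, n = 3, adjusted p = 0.0011), and these counts were the same adjusted over the list alone. Camera called that list lower (adjusted p = 0.00285, and adjusted p = 0.542 with an estimated correlation).

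Lists of biosynthesis and stress were lower as well. In MYC and ribosome biogenesis 17 of 25 fell and 1 rose (20 and 2 adjusted over the list alone). CAD fell by 0.58 ± 0.08, and the gene that rose, NOP2, did so by 0.85 ± 0.06. Camera gave adjusted p = 6.83e-05 (adjusted p = 0.542 with an estimated correlation). In the integrated stress response 13 of 24 fell and 0 rose (15 and 0 adjusted over the list alone), including ATF3 (-1.42 ± 0.20) and the pseudokinase gene TRIB3 (-0.67 ± 0.10), with adjusted p = 5.5e-05 (adjusted p = 0.542 with an estimated correlation). In cholesterol synthesis 11 of 22 fell and 2 rose (12 and 2 adjusted over the list alone). The reductase gene DHCR7 fell by 0.38 ± 0.05, whereas SREBF2 rose by 0.14 ± 0.05, and camera gave adjusted p = 0.00544 (adjusted p = 0.542 with an estimated correlation). Among Sm, LSm and SMN-complex genes 17 of 29 fell and 2 rose by both adjustments, over all genes and adjusted over the list alone, with SNRPA at -0.46 ± 0.08 and SNRPD1, a PRMT5 substrate protein, at -0.40 ± 0.07. The list had adjusted p = 0.0048 (adjusted p = 0.542 with an estimated correlation). Of the PRMT5 complex and other arginine methyltransferases 6 of 12 fell and 0 rose (7 and 0 adjusted over the list alone), with PRMT1, the main asymmetric methyltransferase, at -0.40 ± 0.05, and camera gave adjusted p = 0.0135 (adjusted p = 0.542 with an estimated correlation).

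Lists of B-cell identity, antigen presentation and histones were higher at 96 h. In germinal centre identity 12 of 29 rose and 3 fell by both adjustments, over all genes and adjusted over the list alone, among them MYBL1 (1.21 ± 0.07, from 94.9 ± 1.81 to 219 ± 22.8 CPM, SD, n = 3), NEIL1 (1.09 ± 0.11) and BACH2, a repressor of plasma cell differentiation (0.60 ± 0.06). Camera gave adjusted p = 0.00526 (adjusted p = 0.542 with an estimated correlation). In MHC class II 9 of 13 rose and 0 fell, also adjusted over the list alone, among them HLA-DMB, which loads peptides (0.74 ± 0.08), and the class II transactivator CIITA (0.51 ± 0.08), with adjusted p = 0.00591 (adjusted p = 0.542 with an estimated correlation). Of 14 replication-dependent histone genes 7 rose and 0 fell, also adjusted over the list alone, including HIST1H2BD (0.86 ± 0.13) and HIST1H3H (0.81 ± 0.12), with adjusted p = 0.00115 (adjusted p = 0.542 with an estimated correlation). Since RNA was selected on oligo-dT beads, these counts cover only the histone RNA that the selection kept, not all histone RNA.

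**Figure D2:**
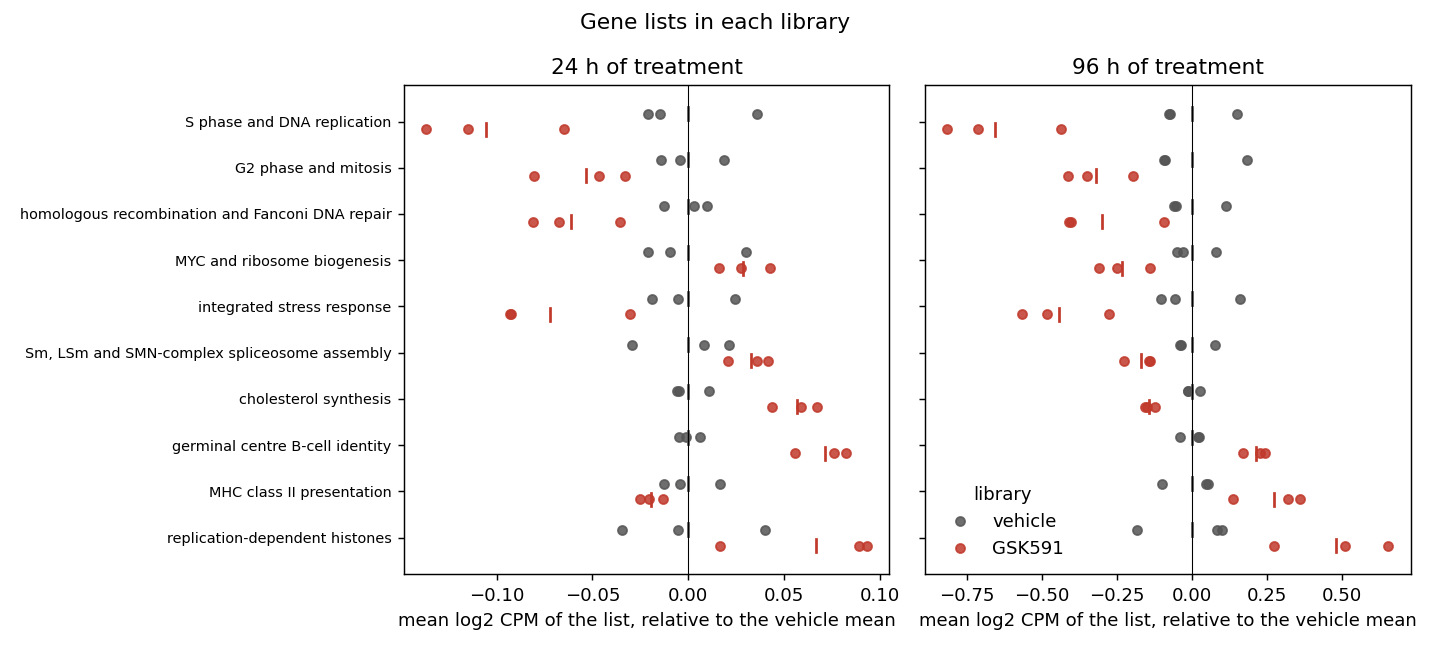
Mean log2 CPM of the members of 10 gene lists in each library, relative to the vehicle mean of the same time (horizontal axis, in log2 units, with a wider scale at 96 h), for vehicle (grey) and GSK591 (red) libraries, with bars at the group means. For S phase and DNA replication the treated libraries lay between -0.14 and -0.06 at 24 h and between -0.82 and -0.44 at 96 h, below every vehicle library of the same time.

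The other lists were not called by camera at 96 h. BCL6-repressed genes went both ways, with 8 of 24 higher and 6 lower (10 and 6 adjusted over the list alone, list adjusted p = 0.68). Those that fell included IRF4 (-0.47 ± 0.06) and CDKN1A. In the plasma cell list 7 of 19 fell and 2 rose (8 and 2 adjusted over the list alone), with XBP1 at -1.24 ± 0.13. Its adjusted p was 0.0781, and 0.0419 without GSK591 replicate 3. Among p53 targets 5 of 29 rose and 6 fell, also adjusted over the list alone, with FDXR at -0.71 ± 0.12 (list adjusted p = 0.725). In the interferon list 9 of 21 fell and 1 rose (10 and 2 adjusted over the list alone), with MX2 at -0.31 ± 0.06 (list adjusted p = 0.0904). That list passed without vehicle replicate 2, GSK591 replicate 1 or GSK591 replicate 3 (adjusted p = 0.0168, 0.0148 and 0.0419). B-cell activation and NF-kB had 4 of 21 higher and 5 lower, also adjusted over the list alone, with the phosphatase gene DUSP2 at -0.61 ± 0.10 (list adjusted p = 0.725). In the BCL2 family 3 of 15 rose, among them the pro-apoptotic BCL2L11 (0.37 ± 0.06), and 1, BCL2A1, fell (-0.89 ± 0.14), also adjusted over the list alone (list adjusted p = 0.433). Of the markers of other cell types, CD14 was called at 0.279 CPM in vehicle and 0.888 in treated cells (1.64 ± 0.35, adjusted p = 0.00751) and COL1A1 was not (adjusted p = 0.188). COL1A1, also below 1 CPM, was called with the replicate block (adjusted p = 0.0171) and without both libraries numbered 2 (adjusted p = 0.0296). With fry, 10 lists were called at 96 h. The lists of G2 phase and mitosis, homologous recombination and MHC class II were not among them (adjusted p = 0.0701, 0.0783 and 0.0701), while the plasma cell and p53 lists were (adjusted p = 0.0202 and 0.0401).

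The same genes were then compared between the times. Across 13091 genes tested at both, log2 fold changes correlated with Pearson r = 0.426 and Spearman rho = 0.474, where genes are not independent replicates. Of 1939 genes called at 24 h, 67.7% were also called at 96 h. Both calls were higher for 668 genes and lower for 614, against 199.5 and 192.7 for independent lists, and 31 genes went in opposite directions. The times share no library. Among genes called at both, the change at 96 h was 2.72 times that at 24 h in the median. Requiring a call at 96 h favours genes with large changes at that time. Over all genes called at 24 h, the slope of the 96 h on the 24 h log2 fold change was 1.48. With only genes of at least 5 CPM in 3 samples, r was 0.629.

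**Figure D3:**
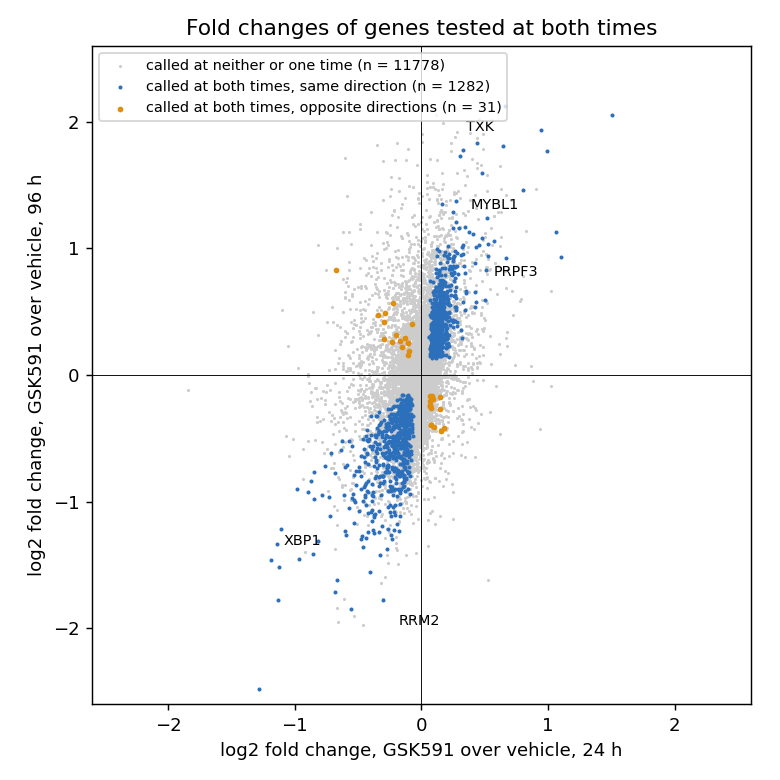
Log2 fold change of GSK591 over vehicle at 24 h (horizontal axis) and 96 h (vertical axis) for 13091 genes tested at both times, 1 point per gene, coloured by whether the gene was called at both times. Of the genes called at both, 31 lay in the quadrants of opposite sign.

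The difference of the effects was tested directly in the fit of all 12 samples. Of 13665 genes, 3298 differed, 1499 with a higher and 1799 with a lower log2 fold change at 96 h. With library size alone the split was 1778 higher and 1474 lower, so which side is larger rests on the scaling. The most positive differences among well-expressed genes were in ENPP3 (1.43 ± 0.16), SYT11 (1.40 ± 0.38) and the calcium-binding protein gene CABP4 (1.29 ± 0.19), and the most negative in RRM2 (-1.48 ± 0.23), thioredoxin (TXN, -1.12 ± 0.14) and E2F7 (-1.10 ± 0.30). CABP4 was low at 24 h, with 2.2 CPM in vehicle and 2.5 in treated cells, against 7.7 and 21.3 at 96 h. Their adjusted p in edgeR's test ran from 0.000227 for ENPP3 to 0.0184 for SYT11. The SYT11 call was lost without GSK591 replicate 2 of 24 h (adjusted p = 0.0517) and with limma-voom (adjusted p = 0.0606). The count of genes fell to 1991 without that same library and to 2034 without vehicle replicate 3 of 24 h, and rose to 5712 without GSK591 replicate 2 of 96 h. Of the 17 lists 11 differed between the times, 3 upwards and 8 downwards, and with an estimated correlation the lowest adjusted p among them was 0.195.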

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

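The results below differed between 24 h and 96 h in the direct test of the difference (log2 fold change at 96 h minus that at 24 h, edgeR for genes and camera for lists). Of the tests in this part, those that leave out single libraries for the S phase and histone lists were chosen only after the result was seen. The fit with the deep library thinned was added after the data were seen.

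Relative to the vehicle of the same time, most of the named genes of proliferation were lower by more at 96 h than at 24 h. The differences were -1.48 for RRM2, -1.10 for E2F7, -0.67 for FANCI, -0.66 for KIF20A, -0.63 for POLA1, -0.59 for CCNA2, -0.58 for GINS2, -0.44 for FANCD2 and -0.37 for TOP2A, while ATM went the other way with 0.86. The medians of the lists differed by -0.58 for S phase and DNA replication, -0.26 for G2 phase and mitosis and -0.32 for homologous recombination and Fanconi repair. The calls of these lists were lost with an estimated correlation (adjusted p = 0.4, 0.476 and 0.495 with an estimated correlation). Such differences also hold changes of the vehicle cells. In vehicle the list of G2 phase and mitosis was higher by 0.429 at 96 h relative to 24 h, with 25 of 30 genes higher and 0 lower. For KIF20A, TOP2A and ATM the treated means were higher at 96 h than at 24 h, and for the other genes named in this paragraph lower.

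The lower S phase list at 96 h was weighed against technical explanations. Its median log2 fold change was -0.662, and -0.669 after removal of the trend with GC content and length, which argues against that trend. Thinning the deep vehicle library left -0.659, and the highest median with 1 library left out was -0.576, without vehicle replicate 2, so neither the depth of that library nor any single library accounts for it. What lies behind the pattern is left open, since the files hold no measure of the cell cycle. Vehicle cells also differed between the times, with a median of -0.295 for this list at 96 h relative to 24 h, and whether time in culture or separate processing of the tables lies behind that may not be told from these data.

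Genes of metabolism, biosynthesis and stress also differed. The differences were -1.12 for TXN, -1.09 for FAH, -1.08 for OXCT1, -0.82 for HSD17B8, -0.44 for ENTPD5, -0.48 for LOC730101, -0.50 for MYC, -0.45 for CAD, 0.67 for NOP2, -1.30 for ATF3, -0.70 for TRIB3 and -0.76 for PSAT1. The list medians differed by -0.34 for MYC and ribosome biogenesis and by -0.36 for the integrated stress response (adjusted p = 0.4 and 0.411 with an estimated correlation). In vehicle the stress response list was higher by 0.375 at 96 h relative to 24 h, with 17 of 24 genes higher and 2 lower, and the list of G2 phase and mitosis by 0.429, so how far their differences rest on the vehicle cells is left open.

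Cholesterol synthesis genes were higher at 24 h and lower at 96 h. The list's median in the direct test was -0.23 (adjusted p = 3.98e-06, and adjusted p = 0.195 with an estimated correlation), and NSDHL, DHCR7 and ACAT2 differed by -0.28, -0.42 and -0.42. The medians of the separate fits differed by -0.206. After removal of the trend with GC content and length that difference was -0.273, and with 1 library left out it stayed at or below -0.194 (without GSK591 replicate 3 of 24 h). A rise of 0.206 in vehicle cells between the times could have produced it. No such rise was seen in the vehicle counts, where the median was -0.0164 with an SD of 0.156 over 22 genes, 4 higher and 9 lower. Since each table holds 1 time, a shift between the tables could hide a change of the vehicle cells, so this comparison cannot decide that explanation. What lies behind the change of direction is left open.

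Differences of the methyltransferase and splicing genes were -0.33 for WDR77, -0.48 for PRMT1, -0.49 for SNRPA, -0.42 for SNRPD1, 0.45 for PRPF3 and 0.30 for SMNDC1. The medians differed by -0.19 for the PRMT5 complex and other arginine methyltransferases and by -0.26 for the Sm, LSm and SMN-complex list (adjusted p = 0.4 for each with an estimated correlation). In vehicle the medians of these lists were also lower at 96 h relative to 24 h. They were -0.306, with 9 of 12 genes lower and 1 higher, and -0.206, with 22 of 29 lower and 0 higher. How far the differences rest on the vehicle cells is left open.

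Genes of B-cell identity and immunity differed by 0.92 for MYBL1, 0.59 for NEIL1, 0.44 for BACH2, 0.57 for NFKBID, -0.91 for XBP1, -0.57 for FKBP11, -0.49 for IRF4, -0.18 for MX2, 0.35 for HLA-DOB, 0.66 for HLA-DMB, 0.43 for CIITA, -0.86 for BCL2A1, -0.58 for DUSP2 and 0.34 for BCL2L11. The p53 targets CDKN1A, FDXR and XPC differed by -0.47, -0.59 and 0.22. The list medians differed by 0.09 for germinal centre identity and 0.28 for MHC class II (adjusted p = 0.4 and 0.416 with an estimated correlation). Large rises at 96 h gave differences of 1.88 for SPOCK2, 1.58 for TXK, 1.43 for ENPP3, 1.40 for SYT11, 1.32 for AHNAK2 and 1.29 for CABP4.

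Histone genes had a median difference of 0.38 (adjusted p = 0.4 with an estimated correlation), with 0.68 for HIST1H2BK, 0.56 for HIST1H2BD and 0.65 for HIST1H3H. At 96 h their median of 0.434 was weighed against 3 explanations. If poly(A) selection had been leakier in treated samples, small nucleolar and small nuclear RNAs were predicted to rise too. The median of 176 such genes was -0.115 (SD 0.483), with 17 higher and 23 lower. Reads at these symbols may come from overlapping genes, which cannot be told apart here, so this test cannot decide that explanation. Reads moving between histone copies would leave the family's sum alone, but the summed CPM of 73 HIST genes rose by a log2 ratio of 0.528, from between 85.8 and 105 CPM in vehicle to between 118 and 153 in treated libraries. HIST1H2BK alone made up a large part of that sum, with a mean of 33.3 CPM in vehicle and 58.4 in treated cells. Of 31 HIST genes tested, 9 were called higher and 0 lower, so the sum does not show a rise across the whole family. The lowest median with 1 library left out was 0.378, without GSK591 replicate 1. What lies behind the rise is left open. The same list was higher by 0.508 in vehicle at 96 h relative to 24 h.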

How the results depend on the processing

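The alternatives added after the data were seen are the thinned library and the fit without both 96 h libraries numbered 2. Among the genes selected by the rule and the lists, no called one changed direction in the alternatives run for it. The remaining called genes were not checked for this. With library size alone, the split of the genes that differed between the times turned to 1778 higher and 1474 lower. With a threshold of 0.01 the counts of genes were 851 at 24 h, 2644 at 96 h and 1275 for the difference, as fewer genes pass a stricter threshold. With all 12 samples in 1 fit, 29 genes were called at 24 h, where the wider spread of the 96 h libraries enters. Without both 96 h libraries numbered 2 the 96 h count was 8201 (the cause was not tested). With 1 library left out, counts of genes ran from 980 to 2208 at 24 h, 3438 to 7485 at 96 h and 1991 to 5712 for the difference, counts of lists from 6 to 9 and 11 to 13, and the correlation of fold changes from 0.355 to 0.442. That correlation was 0.629 with at least 5 CPM in 3 samples, a filter that leaves out the least precise genes. An estimated correlation left 0 lists at 24 h and 0 at 96 h, where 7 and 11 stood with the preset value, and fry called 2 at 24 h. RLE factors, library size alone, DESeq2, limma-voom and no filter kept the total counts of genes within 1.5 times. Of 44 named genes called at 24 h 13 lost the call without some single library, of 46 at 96 h 2 did. The replicate numbers are shared by the groups, but the deviations of same-numbered libraries correlated by 0.021, 0.131 and 0.035 at 24 h and 0.287, 0.248 and 0.013 at 96 h, so pairing was not taken as given. As a replicate block the numbers gave 2811, 6293 and 4167 genes, 6 and 11 lists and r = 0.431, and 3 of 6 libraries at 24 h and 5 of 6 at 96 h correlated best with their own number. The 6 samples of a time allow 10 splits, too few for a share under 0.05. The real split (1 of 10) gave 1940 genes at 24 h and 5437 at 96 h, against a highest other of 0 for each, and 7 and 11 lists, against 5 and 10. Of 100 pairs of splits 1, the real one, reached a correlation of 0.426 (highest other 0.378), which speaks against chance. For the difference 14 of 100 splits gave as many genes (highest other 5919). The 13 others all kept the real 96 h grouping or its mirror, and the 86 that regrouped 96 h gave at most 0 genes. Splits that keep the 96 h grouping still hold the 96 h effect, and they are a set share of the splits that can be drawn. This count therefore cannot decide whether chance lies behind the genes.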

Other observations

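The families in this paragraph were chosen after the data were seen, by symbol, and tested with camera over 17 families at each time. At 96 h genes of mitochondrial and protein machinery were lower. Of 77 mitochondrial ribosomal protein genes 37 fell and 3 rose (median log2 fold change -0.17), with MRPL21 at -0.79 ± 0.08 and MRPS28 at -0.66 ± 0.09. Of 43 genes of complex I and its assembly 15 fell and 1 rose, including NDUFAF3 (-0.70 ± 0.06), and of 18 ATP synthase genes 10 fell and 0 rose, including ATP5H (-0.50 ± 0.06). Proteasome genes fell in 19 of 48 cases and rose in 3, nucleoporins fell in 9 of 21 and rose in 0, and cytosolic ribosomal proteins fell in 13 of 76 and rose in 0. These 6 families had adjusted p between 7.01e-06 and 0.00111, and all lost the call with an estimated correlation (lowest adjusted p = 0.54 with an estimated correlation). At 24 h the cytosolic ribosomal proteins had been called the other way, with 9 of 76 higher and 1 lower (median 0.03, adjusted p = 0.000869, and adjusted p = 0.798 with an estimated correlation). The 96 h medians kept their sign with RLE factors and with library size alone. The 24 h median of the cytosolic ribosomal proteins shrank from 0.0267 to 0.00898 with library size alone, so its size rests on the scaling.

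Other families went up at 96 h. Of 30 interleukin and interleukin receptor genes 13 rose and 2 fell, among them IL2RA (0.89 ± 0.17) and IL11RA (0.81 ± 0.16), and of 41 potassium channel genes 11 rose and 2 fell, among them KCNS1 (1.99 ± 0.19). Both had adjusted p = 0.0308 (adjusted p = 0.54 with an estimated correlation). Of 6 toll-like receptor genes 4 rose, including TLR7 (0.56 ± 0.12), and the family was not called (adjusted p = 0.0939). At 24 h, 67 of 466 genes named only by a LOC number fell and 4 rose (median -0.12, adjusted p = 1.99e-06, and adjusted p = 0.325 with an estimated correlation), whereas at 96 h 86 of 494 fell and 61 rose (adjusted p = 0.315). Whether that family's response differed between the times was not tested.

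Vehicle cells at 96 h differed from vehicle cells at 24 h in 7491 of 13347 genes, 3778 higher and 3713 lower. Genes of MYC and ribosome biogenesis were lower by a median of -0.604 and genes of G2 phase and mitosis higher by 0.429. Time in culture and the separate tables cannot be told apart here, since each table holds 1 time.

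Because PRPF3 and PRPF38B led the 24 h list by p-value, splicing factor families were tested as a hypothesis, leaving out PRPF3, PRPF38B, PRPF4B and LUC7L, which had been seen. Of 118 genes 30 were called at 24 h, 25 higher and 5 lower, such as RBM39 (0.20 ± 0.02) and SRSF4 (0.19 ± 0.02). That share of 25.4% was above that of 86.96% of 10000 random lists matched on size and expression (median 21.2%), so a higher rate of calls than in other genes was not shown. At 96 h 51 were called, 26 higher and 25 lower, above 41.09% of the random lists. Leaving out genes that led the 24 h list lowers the families' share, so this test cannot decide whether the families as a whole change more often. It compared only the rate of calls, and whether their direction at 24 h differs from that of other genes was not tested.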
